A study of Mus musculus with 6 samples.

How the data were processed

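Transcripts were measured by RNA sequencing of total RNA from 2 mouse mammary carcinoma cell lines of BALB/c origin, 4T1 and 4TO7, with 3 libraries per line. The cells were grown in serum-supplemented medium without treatment, RNA was purified on columns and libraries followed a standard Illumina procedure, per the labels' protocols. The labels give no batch, date or sex. They say only that each line was grown in triplicate, not whether the 3 cultures of a line were independent, so every p-value measures the spread between these samples, which may be technical.

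The deposited table lists 47729 genes by Ensembl identifier and symbol. STAR 2.5, featureCounts 1.5, DESeq2 (version not given) and the mouse genome build GRCm38 are named, per the submitters' processing notes. Which annotation release was counted, and whether counting used strand, is not given in the sources used here, so reads of overlapping or antisense genes, and of near-identical copies, may be divided in ways that cannot be traced. The 6 sample columns hold a normalised signal, gene read counts divided by 1 size factor per library, per the file headers and the values. The same deposited table carries the authors' own comparison: a mean normalised count, a log2 fold change with its standard error, a test score that is their ratio, a p-value and an adjusted p-value. Its fold changes are 4TO7 over 4T1 by sign.

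Every nonzero value in each of the 6 columns was a whole multiple of 1 step per library (100% of values within 1e-06 of a whole read), so the read counts could be recovered exactly. Size factors ranged from 0.954 to 1.07. The recovered depth was 36842147, 38789319 and 39072639 reads in 4T1 replicates 1 to 3 and 36191540, 33605566 and 34945421 in 4TO7 replicates 1 to 3. Intervals on ratios of reads are exact 95% intervals and, like the floor of 3 reads used for genes with 0 reads in a line, cover counting error only.

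The values were tested as deposited on the scale log2(value + 1), because they are normalised and not raw counts. Genes with a value of at least 10 in at least 3 of the 6 samples were kept (14276 genes). The lines were compared with limma 3.58.1 in R 4.3.3 (a linear model with group alone, moderated with an intensity trend and robust hyperparameters), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are 4T1 minus 4TO7 throughout, and on the log2(value + 1) scale they understate changes of genes with few reads. A fold stated without log2 is the ratio of the line means. Where a line had 0 reads, the fold is a lower bound against 3 reads over that line's 3 libraries. Where it had 1 to 3 reads, the ratio stands with its counting interval.

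Before the data were examined, the design, the alternatives, 31 gene lists with 662 genes and the rule for naming genes were fixed. The rule takes the 10 genes with the largest fold change per direction (adjusted p under 0.05, no overlap between the lines, a mean of at least 100 in the higher line, a regular symbol), up to 4 members of each list with the largest fold change among those that passed, and a fixed set (Cdh1, Epcam, Vim, Zeb1, Fn1, Csf3, Cd274, B2m, Mki67, Xist, Trp53, Hras, Nr2f1 and Twist1). Other genes named in the text were chosen after their values were seen. Of the 662 list genes, 661 were found in the table, with older symbols matched through reference tables, and 499 passed the low-value filter; H2-L was not matched. Lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the 30 lists that had tested members. An estimated correlation, and fry, which asks whether a list moves on balance by itself, were alternatives. Shares per library were compared with exact permutation tests, which cannot go below p = 0.1 with 3 against 3.

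The pipeline was tested on simulated counts for this comparison, 14276 genes of which 200 were changed. limma recovered 5.97% of genes changed 1.5-fold, 58.2% of genes changed 2-fold and 95.5% of genes changed 4-fold, and 3.64% of its calls were false. edgeR 4.0.16 recovered 58.2% and DESeq2 1.42.0 71.6% of the 2-fold changes, with 4.46% and 17.9% of calls false. The real comparison called 6997 of 14276 genes, far more than were changed in the simulation, and the adjusted threshold depends on that share. The simulated shares of recovered genes and false calls therefore do not carry over to it. In a simulation of list tests, camera at the preset correlation called 4 of 200 unchanged lists at p under 0.05 and gave the changed list p = 7.14e-39. With an estimated correlation it called 0 of 200 at that unadjusted level and gave the changed list p = 0.00014. Genes were simulated independently of each other, so this could not test how the preset correlation serves lists of correlated genes.

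Alternatives changed the pseudocount, the low-value filter, the scaling, the variance model, the set test and the libraries used, added the replicate number as a block, and ran edgeR and DESeq2 on the recovered reads. Gene positions, lengths and GC content came from GENCODE M21 on GRCm38, in which 99.7% of the tested identifiers were found. For the closing section, neighbouring genes were compared in blocks of 40 genes and by a search for 1 change point per chromosome. The search called 3% of simulated chromosomes without a shift and 100% of those with a shift of 0.6. Each simulated chromosome held 500 randomly drawn genes, with the shift placed at the middle. The simulation therefore did not test other gene numbers, change points near an end or neighbours that vary together.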

Results

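RNA was sequenced from 4T1 and 4TO7, a pair of mouse lines derived from mammary carcinoma of the BALB/c strain. As background, 4T1 is widely used because it spreads from the mammary gland to lung and other organs and grows there, whereas 4TO7 cells disseminate but seldom form visible metastases. Each line had 3 libraries of 33605566 to 39072639 reads assigned to genes. On log2 values the 3 4T1 libraries correlated across genes at r = 0.988 to 0.99 and the 3 4TO7 libraries at 0.978 to 0.993, against 0.809 to 0.848 between lines. The line separated the libraries along the first principal component, which held 89.9% of the variance. The second component, with 5.27%, set 4TO7 replicate 2 (score 52.2) apart from 4TO7 replicates 1 and 3 (-20.0 and -27.5). No pair of replicates was alike within sampling noise (chi-square of at least 24.8 per gene). Values below are normalised read counts, mean ± SD with n = 3 per line, and adjusted p-values are from limma unless another test is named.

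The comparison of 4T1 with 4TO7 asks which transcripts differ between the lines; the labels state no further purpose. 4T1 had higher levels of epithelial genes such as Krt7, Cldn3, Cdh1 and Epcam, together with cytokines such as Il1a and Csf3 and enzymes of cholesterol synthesis. 4TO7 instead had higher levels of Nr2f1, Csn3, Pdgfra, collagen VI chains and several interferon-stimulated genes. Twist1, a transcription factor best known for driving mesenchymal change, was present in the line with the epithelial genes. Vim, the mesenchymal intermediate filament, was abundant in both lines (112400 ± 8646 in 4T1 and 97123 ± 9632 in 4TO7) and did not pass (adjusted p = 0.198).

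Of 14276 genes tested, 3585 were higher in 4T1 and 3412 higher in 4TO7, 49% in all, and 1895 and 2030 of them differed by at least 2-fold on the fitted scale. The 3 values of one line lay wholly above those of the other in 8342 genes (58.4%), where chance gives 10%. Among protein-coding genes, 3268 of 12084 were higher in 4T1 and 2956 higher in 4TO7. Some genes were read in a single line: 137 had a 4T1 mean of at least 100 with at most 3 reads over the 4TO7 libraries, and 57 showed the opposite. Leaving out 4TO7 replicate 2 gave 4162 and 3902 genes.

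The largest differences toward 4T1 were in Nptx1, Il1a, Fads1, Kcnk1, Krt7, Lamb3, Moxd1, Krt19, Fbln2 and Esrp1. Nptx1, which encodes a secreted neuronal pentraxin (ENSMUSG00000025582, chromosome 11, 119538719 to 119547753), had 9159 ± 880 normalised counts in 4T1 and 3 reads in all of 4TO7, a ratio of 9231 (95% interval 3158.5 to 44766; 17477 as the ratio of means without 4TO7 replicate 3). Krt7, a keratin of simple epithelia (ENSMUSG00000023039, chromosome 15, 101411043 to 101430313), had 42229 ± 3719 against 13.6 ± 4.66. Fads1, a fatty acid desaturase, had 5483 ± 129 against 2 reads. Moxd1 had 2499 ± 450 in 4T1 and 0 reads in 4TO7, at least 2522-fold higher. Esrp1, a splicing regulator of epithelial cells, had 3457 ± 593 against 3 reads, all in 4TO7 replicate 3. Adjusted p for these 10 genes lay between 7.12e-08 and 1.15e-06.

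Toward 4TO7, the largest differences were in Col9a1, Rcn3, Ppap2b, Medag, Nxf3, Prickle2, Hdgfrp3, Xlr3a, Esm1 and Rassf4. Col9a1, a collagen IX chain typical of cartilage (ENSMUSG00000026147, chromosome 1, 24177610 to 24252684), had 5850 ± 3614 in 4TO7 and 2 reads in 4T1. Ppap2b, a lipid phosphate phosphatase, had 1387 ± 447 in 4TO7 and 0 reads in 4T1, at least 1401-fold higher. Prickle2, a planar cell polarity gene, had 956 ± 210.1 and 0 reads, at least 966-fold higher. Esm1, an endothelial proteoglycan, had 4055 ± 689 against 4.64 ± 1.61. Xlr3a, on the X chromosome, belongs to a family of near-identical copies, so its 948 ± 69.9 normalised counts may be shared among them. Adjusted p for the 10 genes lay between 1.13e-07 (Rassf4) and 1.41e-06 (Col9a1).

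Epithelial genes formed the clearest group. Of 21 junction and keratin genes tested, 20 were higher in 4T1 and 0 higher in 4TO7, with a median log2 fold change of 7.70 (20 and 1 adjusted over the list alone). Cdh1, the epithelial cadherin (chromosome 8, 106603351 to 106670246), had 19351 ± 2121 in 4T1 and 169.7 ± 44.6 in 4TO7, a log2 fold change of 6.85 ± 0.20 (SE). Epcam had 16980 ± 1871 against 23.7 ± 9.25. Cldn3, a tight junction claudin, had 3736 ± 491 against 1.34 ± 0.65. Krt18 was only 4.64-fold higher, with 13535 ± 4763 remaining in 4TO7. The tight junction gene F11r, named after its value was seen, was the 1 member that did not pass, at 3816 ± 211 against 4650 ± 292. camera placed the list above other genes (adjusted p = 8.31e-13 at the preset correlation, adjusted p = 0.747 with an estimated correlation). In 4TO7 replicate 2 the list lay lower than in the other 4TO7 libraries by a median of -0.87 (log2).

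Epithelial transcription factors, splicing factors and proteases followed the same direction, with 16 of 17 higher in 4T1 and 0 higher in 4TO7 (16 and 0 adjusted over the list alone; median log2 fold change 5.05). Besides Esrp1, these included Myo5b, a motor of apical trafficking, at 1403 ± 274 against 1.69 ± 1.26. Ap1m2, an epithelial adaptor subunit, had 584 ± 76.4 against 1 read. Ovol1, a repressor of mesenchymal genes, had 209 ± 62.7 against 1 read. camera gave adjusted p = 3.3e-10, and adjusted p = 0.31 with an estimated correlation. 4TO7 replicate 2 lay lower for this list by a median of -0.48.

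**Figure D1:**
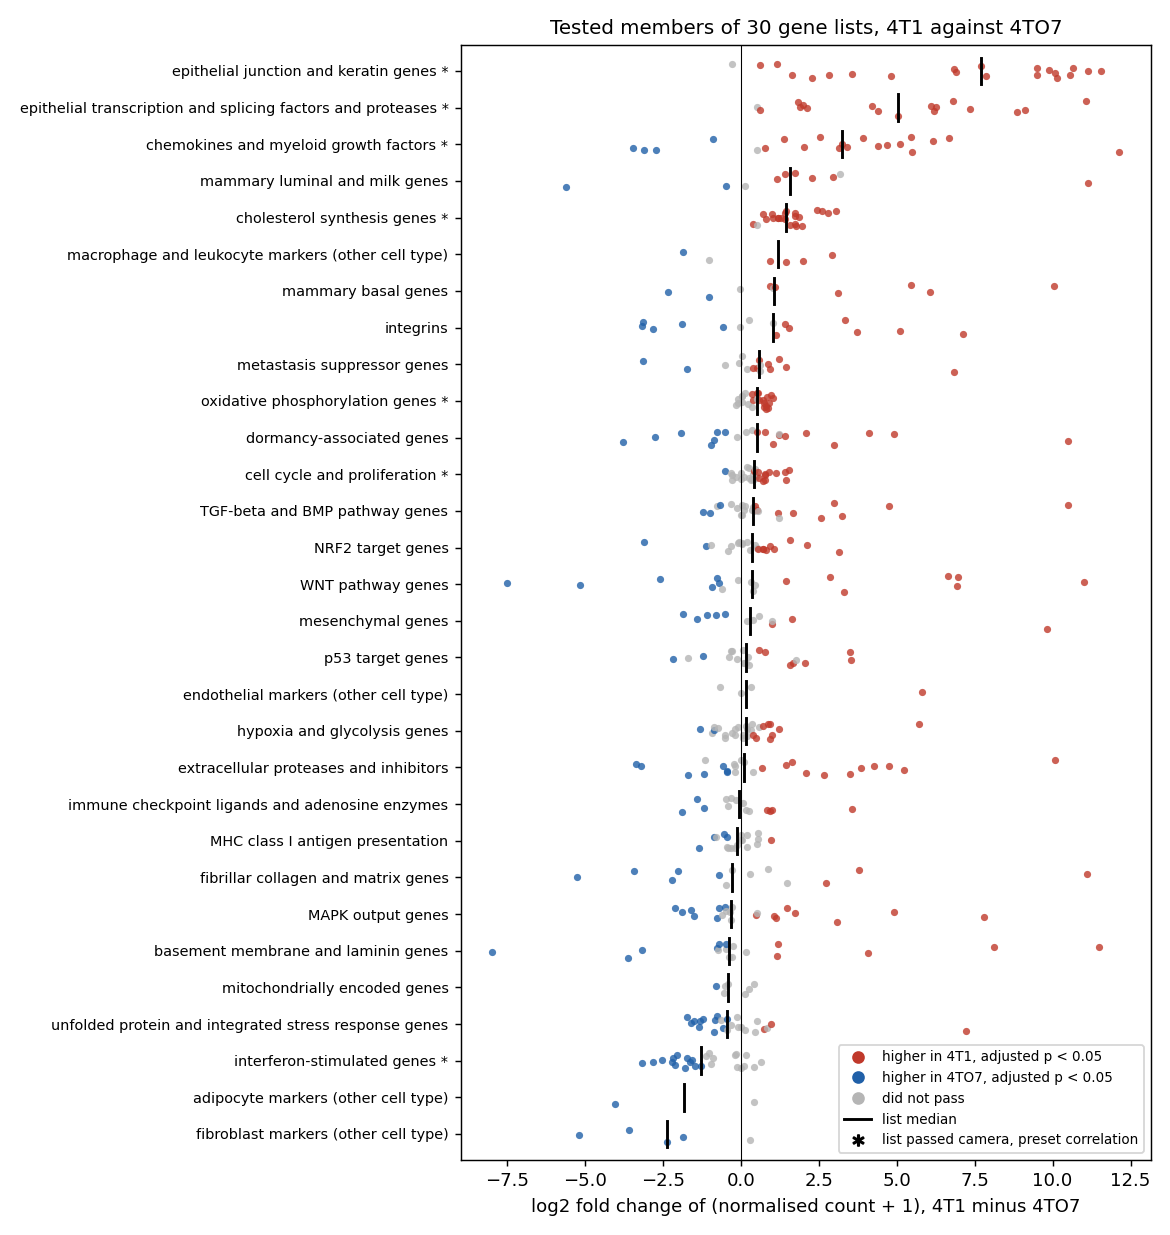
Log2 fold change of (normalised count + 1), 4T1 minus 4TO7, for each tested member of 30 gene lists (1 point per gene, from 3 libraries per line), coloured by whether it passed at adjusted p under 0.05; black bars are list medians and asterisks mark the 7 lists that passed camera at the preset correlation. The epithelial junction list has its median at 7.70 and the interferon-stimulated list at -1.27; 0 lists passed with an estimated correlation.

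Mesenchymal genes went both ways. Of 20 in the list 12 were tested, 3 of them higher in 4T1 and 5 higher in 4TO7, as adjusted over the list alone. The list was not called by camera (adjusted p = 0.933). Twist1 (chromosome 12, 33957671 to 33959829) had 1155 ± 114 in 4T1 and 1 read in 4TO7, in replicate 2, a ratio of 3493 (95% interval 626 to 137990). Fn1, fibronectin, was 2.94-fold higher in 4T1 at 105150 ± 9006 against 35762 ± 14645. Zeb2, a repressor of Cdh1, was 2.63-fold higher in 4TO7 at 5009 ± 246 against 1907 ± 410.3. Zeb1 was low in both lines (29.3 ± 11.9 and 14.9 ± 8.07; adjusted p = 0.113). Pdgfrb was 3.85-fold higher in 4TO7 at 25.1 ± 13.8 normalised counts (7.16-fold without 4T1 replicate 3), a call lost without 4T1 replicate 1 (adjusted p = 0.114), 4T1 replicate 2 (0.115), 4TO7 replicate 1 (0.0921) or 4TO7 replicate 3 (0.106).

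Matrix genes also divided by chain. Of 23 fibrillar collagen and matrix genes 13 were tested, 3 of them higher in 4T1 and 5 higher in 4TO7. Of 17 basement membrane genes tested, 5 were higher in 4T1 and 6 higher in 4TO7. Both lists had the same counts adjusted over the list alone. Col6a2 and Col6a3, chains of collagen VI, were 13.2-fold and 61.3-fold higher in 4TO7, at 808 ± 485 and 100.2 ± 41.0, Col6a3 99.9-fold without 4T1 replicate 3. Fbln2, a basement membrane fibulin, had 15853 ± 1856 in 4T1 against 6.23 ± 1.14. Lama3, a laminin chain of epithelia, had 3491 ± 1300 in 4T1 against 11.3 ± 4.28. Lama4, a chain of mesenchymal laminins, had 3329 ± 1548 in 4TO7 against 12.8 ± 7.20. Neither list was called (adjusted p = 0.571 and 0.559), and in both the median and camera pointed to 4TO7 while the mean pointed to 4T1. In 4TO7 replicate 2 the fibrillar matrix list lay lower than in the other 4TO7 libraries by a median of -0.81 (log2), the mesenchymal list by -0.49 and the basement membrane list by -0.37. Without it, 5 and 8 basement membrane genes were called.

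Integrins numbered 7 of 15 higher in 4T1 and 5 higher in 4TO7 (8 and 5 adjusted over the list alone; list adjusted p = 0.355). Itgb6, an epithelial integrin, had 140 ± 30.5 in 4T1 and 0 reads in 4TO7, at least 141-fold higher. Itga2, a collagen receptor subunit, had 4794 ± 2006 against 132 ± 35.4. Of 25 extracellular proteases and inhibitors, 11 were higher in 4T1 and 7 higher in 4TO7, as adjusted over the list alone (list adjusted p = 0.328), and 11 and 9 without 4TO7 replicate 2. Adam12 had 1380 ± 299 in 4T1 and 1 read in 4TO7. Adamts5, which cleaves aggrecan, had 38.2 ± 14.8 in 4T1 and 0 reads in 4TO7.

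Chemokines and myeloid growth factors were mostly higher in 4T1, in 16 of 21 genes, with 4 higher in 4TO7 (16 and 4 adjusted over the list alone; median log2 fold change 3.26). Il1a had 8587 ± 3767 in 4T1 and 3 reads in 4TO7. Csf3, the granulocyte colony-stimulating factor, was higher at 8560 ± 1585 against 1070 ± 638. Cxcl16 was 72.8-fold and Ccl2, a monocyte chemoattractant, 159-fold higher, Ccl2 at 316 ± 91.3 against 1.99 ± 0.11. The 4 members higher in 4TO7 were Il33, Il11, Tslp and Cxcl10, chosen here after their values were seen. camera gave adjusted p = 0.000432, and adjusted p = 0.782 with an estimated correlation. 4TO7 replicate 2 lay lower for this list by a median of -0.48, with Csf3 at 519 against 1769 and 921 in replicates 1 and 3.

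Interferon-stimulated genes were higher in 4TO7 in 13 of 25 cases and in 0 cases higher in 4T1 (14 and 0 adjusted over the list alone), with a median log2 fold change of -1.27. Ifi44 had 406 ± 286 in 4TO7 against 32.9 ± 7.66 in 4T1, and Zbp1, a sensor of nucleic acids, 280.4 ± 199.8 against 28.9 ± 8.45. Irf7 had 477 ± 320.5 against 83.9 ± 40.2. camera gave adjusted p = 0.0138 for the list, and adjusted p = 0.782 with an estimated correlation. In 4TO7 replicate 2 the list lay lower than in the other 4TO7 libraries by a median of -1.52 (log2), and without that library 18 of 25 genes were higher in 4TO7. The list's call was lost without 4T1 replicate 1 (adjusted p = 0.0616) or 4TO7 replicate 1 (0.0672) and with edgeR (0.052), Zbp1's and Usp18's without 4T1 replicate 1 (0.0519 and 0.0513) and Usp18's also without 4T1 replicate 2 (0.0527). That of Irf7 was lost without any 1 of the libraries other than 4T1 replicate 3 and 4TO7 replicate 2 (0.0702 to 0.0957).

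Of 19 genes of MHC class I presentation, 1 was higher in 4T1 and 4 higher in 4TO7 (1 and 2 adjusted over the list alone; list adjusted p = 0.458). Calr, an endoplasmic reticulum chaperone, was 2.49-fold higher in 4TO7 at 74607 ± 11749, and Psmb10, an immunoproteasome subunit, 1.91-fold higher in 4T1. B2m had 19153 ± 2486 in 4T1 and 26254 ± 6646 in 4TO7 and did not pass (adjusted p = 0.123); without 4TO7 replicate 2, which lay lower for this list by a median of -0.76, it passed (0.00425), as did the list (0.0235), with 8 genes higher in 4TO7 and 1 higher in 4T1. Over all 6 libraries, camera with an estimated correlation gave the MHC class I list adjusted p = 0.857. Of 23 checkpoint ligands and adenosine enzymes 14 were tested. Of these, 4 were higher in 4T1 and 3 higher in 4TO7, as adjusted over the list alone (list adjusted p = 0.869). Without 4TO7 replicate 2 the counts were 3 and 4. Icosl had 140.4 ± 13.0 in 4T1 against 12.2 ± 7.72, while the NKG2D ligands Raet1d, Raet1e and Ulbp1 were 3.69-fold, 2.30-fold and 2.53-fold higher in 4TO7. Raet1d lies within the annotated span of Raet1e, so reads may be divided between them and they may not be separate results. Cd274, which encodes PD-L1, had 73.5 ± 7.28 in 4T1 and 41.5 ± 12.7 in 4TO7, with an adjusted p of 0.0445 that rose to between 0.069 and 0.124 when any library but 4TO7 replicate 1 was left out. Its call was also lost with equal totals per sample (0.0829), without a low-value filter (0.059), with edgeR (0.0573) and with DESeq2 (0.0544).

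Dormancy-associated genes showed no common direction, with 10 of 21 higher in 4T1 and 7 higher in 4TO7, as adjusted over the list alone (list adjusted p = 0.485). Nr2f1, an orphan nuclear receptor studied as a dormancy regulator (ENSMUSG00000069171, chromosome 13, 78188973 to 78199757), had 10155 ± 2226 in 4TO7 and 723 ± 17.3 in 4T1, a log2 fold change of -3.79 ± 0.18 (SE; adjusted p = 1.13e-06). Bmp7 had 2958 ± 624 in 4T1 against 1.34 ± 1.51. Lifr, the receptor of leukaemia inhibitory factor, had 29.3 ± 2.87 in 4T1 and 0 reads in 4TO7, at least 29.6-fold higher.

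Of 25 TGF-beta and BMP pathway genes, 9 were higher in 4T1 and 3 higher in 4TO7 (10 and 3 adjusted over the list alone; list adjusted p = 0.146). Without 4TO7 replicate 2 the counts were 9 and 5, and the list was called without 4TO7 replicate 3 (0.0495) or without a low-value filter (0.0428). Over all 6 libraries, camera with an estimated correlation gave it adjusted p = 0.782. Ltbp2 had 3205 ± 828 in 4T1 against 159 ± 119, and the ligand Tgfb2 112 ± 2.28 against 14.0 ± 5.28. Of 30 WNT genes 18 were tested and went both ways, 7 higher in 4T1 and 6 higher in 4TO7 (8 and 6 adjusted over the list alone). For the WNT list camera gave adjusted p = 0.456. Wnt7a had 2104 ± 530.2 in 4T1 and 0 reads in 4TO7, at least 2123-fold higher, whereas Wnt6 had 407 ± 184 in 4TO7 against 1.34 ± 1.16. MAPK output genes were 8 of 21 higher in 4T1 and 7 higher in 4TO7, as adjusted over the list alone (list adjusted p = 0.801, with the mean opposite in sign to the median and camera). Without 4TO7 replicate 2 the counts were 9 and 10. The immediate early gene Egr1 was 31.1-fold and the growth factor Hbegf 8.14-fold higher in 4T1, while the ETS factor Etv5 was 4.45-fold higher in 4TO7. Hras had 2394 ± 553 and 1985 ± 742 and did not pass (adjusted p = 0.39; 0.0405 without 4TO7 replicate 2).

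**Figure D2:**
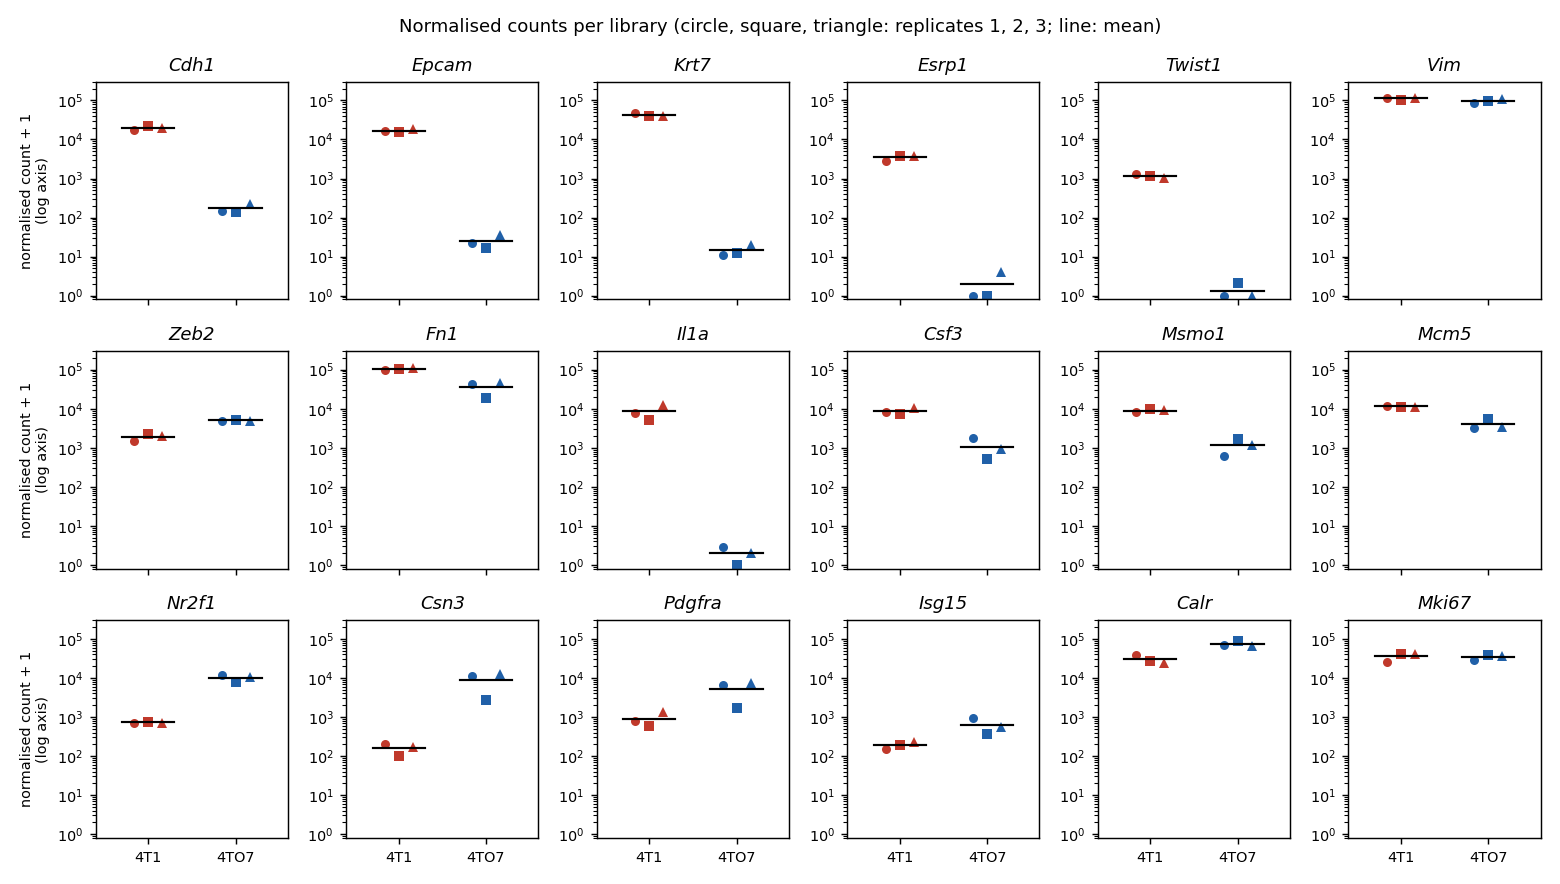
Normalised read count + 1 (log axis) of 18 genes in each library, with 3 libraries of 4T1 (red) and 3 of 4TO7 (blue); circles, squares and triangles are replicates 1, 2 and 3 and lines are means. Cdh1, Epcam, Krt7, Esrp1, Twist1 and Il1a separate the lines by more than 100-fold, Vim and Mki67 lie at similar levels, and 4TO7 replicate 2 (blue square) is the lowest 4TO7 library for Fn1, Csf3, Csn3, Pdgfra and Isg15.

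Genes of the cell cycle leaned to 4T1, with 12 of 30 higher there and 1 higher in 4TO7 (11 and 1 adjusted over the list alone; median log2 fold change 0.43). The replication helicase subunits Mcm5 and Mcm3 were 2.86-fold and 2.67-fold higher, Mcm5 at 11462 ± 420.4 against 4013 ± 1171. The proliferation marker Mki67 had 35978 ± 9349 and 35167 ± 5303 and did not pass (adjusted p = 0.98). camera gave adjusted p = 0.0254, and adjusted p = 0.782 with an estimated correlation. Its call was lost without 4TO7 replicate 1 (0.0998) or 4TO7 replicate 3 (0.0626), with quantile normalisation (0.0848), with edgeR (0.166) and with DESeq2 (0.14). Without 4TO7 replicate 2, which lay higher for this list by a median of 0.48, 20 of 30 genes were higher in 4T1.

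Transcripts of cholesterol synthesis genes were higher in 4T1 almost throughout the list. Of 23 genes tested, 22 passed and 0 were higher in 4TO7 (23 and 0 adjusted over the list alone, median log2 fold change 1.44). Msmo1, a sterol oxidase, was 7.70-fold higher at 8995 ± 613 against 1169 ± 530. Hmgcs1, an enzyme of an early step, was 6.92-fold higher. camera gave adjusted p = 9.2e-09, and adjusted p = 0.747 with an estimated correlation. Genes of oxidative phosphorylation encoded in the nucleus were higher in 4T1 in 15 of 25 cases, with 0 higher in 4TO7 (15 and 0 adjusted over the list alone; median 0.53). Uqcrc1 of complex III and Atp5b of the ATP synthase were 2.07-fold and 1.95-fold higher. For that list camera gave adjusted p = 0.00568, and adjusted p = 0.782 with an estimated correlation, and the call was lost with edgeR (0.0968) and DESeq2 (0.0598) on the recovered reads.

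Among stress responses, 11 of 24 genes of the unfolded protein and integrated stress response were higher in 4TO7 and 3 higher in 4T1, as adjusted over the list alone (list adjusted p = 0.148). The disulfide isomerases Pdia6 and Pdia4 were 3.31-fold and 3.01-fold higher in 4TO7, Pdia6 at 41285 ± 679 against 12488 ± 1934. Vldlr, a lipoprotein receptor in the same list, had 164 ± 90.2 in 4T1 and 0 reads in 4TO7, at least 165-fold higher. Hypoxia and glycolysis genes were 9 of 28 higher in 4T1 and 2 higher in 4TO7 (4 and 1 adjusted over the list alone; list adjusted p = 0.485), with counts of 7 and 6 without 4TO7 replicate 2. Adm was 43.1-fold higher in 4T1 (103-fold without 4TO7 replicate 3) and Vegfa, the angiogenic growth factor, 2.47-fold higher in 4TO7. Of 22 NRF2 targets, 9 were higher in 4T1 and 2 higher in 4TO7, as adjusted over the list alone (list adjusted p = 0.236). The transporter Abcc4 was 8.18-fold higher in 4T1 (12.4-fold without 4TO7 replicate 2) and Gstm1, a glutathione transferase, 9.48-fold higher in 4TO7. Of 21 p53 targets, 7 were higher in 4T1 and 2 higher in 4TO7, as adjusted over the list alone (list adjusted p = 0.383), with Perp 11.5-fold higher in 4T1 and Phlda3 4.83-fold higher in 4TO7. Trp53 itself had 1362 ± 366 and 1164 ± 68.1 and did not pass (adjusted p = 0.461).

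Tested markers of both mammary lineages were higher in 4T1 more often than in 4TO7, but many were below the filter. Of 24 mammary luminal and milk genes 10 were tested, 6 of them higher in 4T1 and 2 higher in 4TO7. Of 20 basal genes 10 were tested, likewise 6 and 2. Each list had 7 and 2 adjusted over the list alone, and camera gave adjusted p = 0.104 for both. edgeR called both lists (0.0137 luminal, 0.0111 basal), and the luminal list was also called without 4TO7 replicate 3 (0.0495). With an estimated correlation over all 6 libraries, camera gave adjusted p = 0.782 (luminal) and 0.747 (basal). Krt14, a basal keratin, had 1363 ± 249 in 4T1 and 1 read in 4TO7, and Esr1, the oestrogen receptor, was 7.44-fold higher in 4T1. Csn3, the milk protein kappa-casein, was 56.9-fold higher in 4TO7 at 8803 ± 5352 against 155 ± 51.5, and 4TO7 replicate 2 lay lower for the luminal list by a median of -0.90. Among 16 metastasis suppressor genes, 8 were higher in 4T1 and 2 higher in 4TO7 (9 and 2 adjusted over the list alone; list adjusted p = 0.236). Besides Cdh1, Gsn, which encodes the actin-severing protein gelsolin, was 2.58-fold higher in 4T1. Arhgdib had 6429 ± 380.5 in 4TO7 against 733 ± 90.5, and Pdcd4, an inhibitor of translation, was 3.12-fold higher in 4TO7.

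Markers of other cell types were mostly below the filter. Of 15 fibroblast markers 5 were tested, 4 of them higher in 4TO7 and 0 higher in 4T1, as adjusted over the list alone (list adjusted p = 0.111; 0.0166 without 4TO7 replicate 2). Over all 6 libraries, camera with an estimated correlation gave the fibroblast list adjusted p = 0.782. Pdgfra had 5286 ± 3123 in 4TO7 against 897 ± 399 in 4T1, and in 4TO7 replicate 2 the list lay lower than in the other 4TO7 libraries by a median of -2.05. Of 22 macrophage and leukocyte markers 6 were tested, 4 higher in 4T1 and 1 higher in 4TO7 (4 and 2 adjusted over the list alone and also without 4TO7 replicate 2; list adjusted p = 0.458), with Csf1r at 28.0 ± 6.34 in 4T1 and Cd68 at 323 ± 102. Of 4 endothelial markers tested, 1, Eng, was higher in 4T1 at 2681 ± 286 against 53.1 ± 28.4, and of 2 adipocyte markers 1, Plin4, was higher in 4TO7 at 21.2 ± 11.9, both as adjusted over the list alone (list adjusted p = 0.485 for both). None of the 9 sex-linked genes passed the filter: Xist had 6 reads in 4T1 and 3 in 4TO7, and the Y-linked genes Ddx3y and Uty had 0 reads in all 6 libraries.

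Mitochondrially encoded genes took 1.12 ± 0.17% of values in 4T1 and 1.42 ± 0.26% in 4TO7 (n = 3 each, exact permutation p = 0.3, two-sided, where 0.1 is the smallest possible). The difference of -0.297 percentage points became -0.147 without 4TO7 replicate 3. That share counts every gene whose symbol begins with mt-, not only the 13 genes of the list. Of the 13, 7 were tested, and mt-Co2, mt-Co3 and mt-Atp6, among others, averaged under 4 normalised counts. Of the 7, 1 gene, mt-Nd5, was higher in 4TO7, at 51137 ± 8867 against 29491 ± 4332, and 0 were higher in 4T1, as adjusted over the list alone (list adjusted p = 0.531); without 4TO7 replicate 2 the counts were 4 and 1. The 10 most abundant genes took 4.34 ± 0.23% and 4.17 ± 0.38% (n = 3 each, exact permutation p = 0.5, two-sided).

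The authors' deposited table gives adjusted p-values for 19556 genes, of which 3796 were higher in 4T1 and 3844 higher in 4TO7 at the same threshold. Of these, 3498 and 3313 were also called here in the same direction, and 0 in the opposite direction. Fold changes of the authors' deposited table correlated with those given here at r = 0.991 across genes, which are not independent replicates. Among the tested genes, 186 were called here and not in the authors' deposited table, and 264 only there.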

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

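The alternatives that left out 1 library for the mitochondrial share and the chromosome medians were chosen after seeing the data; the others were planned. The counts of genes higher in each line stayed within 1.5 times their value under every alternative run (2751 to 4162 higher in 4T1, 2491 to 4060 higher in 4TO7). edgeR called 3326 and 3641 genes and DESeq2 3641 and 3665 on the recovered reads, sharing 6726 and 6836 of the 6997 genes called here. Equal totals per sample moved the median of all genes from 0.03 to -0.10 (log2) and the share of calls higher in 4T1 from 51.2% to 42.2%. Of 131 named genes, 115 kept their direction and side of the threshold under every alternative, over 2213 comparisons of which 42 lost and 3 gained a call and 7 reversed. Of 568 comparisons over 30 lists, 19 lost and 20 gained a call and 15 reversed. Folds of genes with 0 to 3 reads in a line are bounds or wide intervals.

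With the replicate number as a block (replicate block), 3990 and 3760 genes were called, 7750 in all, of which 6952 were among the 6997. Deviations of same-numbered libraries correlated at r = -0.01, 0.27 and 0.33, and those of differently numbered libraries at -0.39 to 0.27. These values do not settle whether the numbers pair the libraries. 4T1 replicates 2 and 3 correlated best with their own number, but 4T1 replicate 1 correlated best with 4TO7 replicate 2 (0.11).

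An estimated correlation left 0 of the 7 called lists (1 at unadjusted p under 0.05), with adjusted p of 0.747 for the junction and cholesterol lists, 0.31 for the epithelial factor list and 0.782 for the chemokine, interferon, cell cycle and oxidative phosphorylation lists. fry called 20 lists, but not the interferon (0.179) or cell cycle (0.088) list. fry also turned fibrillar collagen (0.0197), basement membrane (0.226), checkpoint (0.88) and MAPK (0.0152) toward 4T1. With edgeR the interferon (0.052), cell cycle (0.166) and oxidative phosphorylation (0.0968) lists lost their call and fibrillar collagen (0.758), basement membrane (0.698) and MAPK (0.875) turned. With DESeq2 cell cycle (0.14) and oxidative phosphorylation (0.0598) lost it and mesenchymal, fibrillar collagen, basement membrane (0.981 each) and MAPK (0.91) turned. Quantile normalisation ended the cell cycle call (0.0848) and turned the mesenchymal list (0.995) and Mki67 (-0.18). Without a filter the checkpoint list turned (0.771). With 1 library left out, adjusted p ranged from 9.81e-06 to 0.0672 for the interferon list and from 0.000474 to 0.0998 for cell cycle, and that of the mesenchymal genes from 0.768 (without 4TO7 replicate 3) to 0.984 (without 4T1 replicate 3), turned in 2 cases (0.926 and 0.946). Mki67 turned with equal totals (-0.12), edgeR (-0.01) and without each of 3 libraries in turn (range over all 6 from -0.12 to 0.25), and Trp53 without 4T1 replicate 1 (range -0.0049 to 0.38). The cause was not tested.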

Other observations

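The gene families, the blocks of neighbouring genes and the deviation of 4TO7 replicate 2 were examined only after the results were seen, and the tests of 4T1 RNA and of fibroblast transcripts were set after some of their values were known. Among 199 families of protein-coding genes that share a symbol stem, the Eif genes leaned to 4T1. Of the 51, 25 were higher there and 2 higher in 4TO7 (median log2 fold change 0.42, 0.29 with equal totals per sample). The stem takes in translation initiation factors but also genes that restrain initiation, such as Eif2ak4 and Eif4ebp2, both among the 25. Eif5a, which helps ribosomes through difficult peptide bonds, had 57050 ± 9727 normalised counts in 4T1 and 22180 ± 7837 in 4TO7, and its paralogue Eif5a2 had 810 ± 260 against 0 reads. camera gave the family adjusted p = 0.0035, and adjusted p = 1 with an estimated correlation. The lean was not particular to Eif genes. The ribosomal protein stems Mrpl and Rpl also leaned to 4T1 (medians 0.37 and 0.35, camera adjusted p = 0.036 and 0.044). So did Krt and Cldn (camera adjusted p = 0.00044 and 0.0029). None of these passed with an estimated correlation. In 4TO7 replicate 2, 40 of the 51 Eif genes were above both other 4TO7 libraries (median 0.31), toward the 4T1 level. Genes of intraflagellar transport, which build the primary cilium, were higher in 4TO7 in 9 of 14 cases and higher in 4T1 in 1 (median -0.96, -1.09 with equal totals; camera adjusted p = 0.047, and adjusted p = 1 with an estimated correlation). Ift122 had 1688 ± 540.5 in 4TO7 against 442 ± 93.8, and Ift27 390.5 ± 70.5 against 83.8 ± 19.1, while 13 of the 14 lay lower in 4TO7 replicate 2 than in both other 4TO7 libraries (median -0.53). Of 17 semaphorins, a family of guidance signals, 10 were higher in 4TO7 and 3 higher in 4T1 (camera adjusted p = 0.16), with Sema3b at 6141 ± 2807 against 274 ± 17.9 and a median deviation of -0.72 in 4TO7 replicate 2.

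Cdkn2a and Cdkn2b, neighbouring cell cycle inhibitor genes on chromosome 4 (GRCm38, 89274471 to 89294653 and 89306299 to 89311039), had 0 reads in all 6 libraries. Mtap, which ends at position 89181081, had 40611 ± 2549 normalised counts in 4T1 and 43196 ± 1210 in 4TO7. Klhl9, on the far side of Mtap, had 3406 ± 866 and 4637 ± 491. On the other side of the inhibitor genes, Dmrta1 (89679436 to 89694772) had 0 reads in 4T1 and 8 in 4TO7. The genes read here therefore do not bound the silent stretch on that side.

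Neighbouring genes differed together between the lines. Over 10983 genes with a mean of at least 100, the SD of the median log2 fold change of 265 blocks of 40 genes was 0.328, against at most 0.156 in 1000 shuffled gene orders, and a spline on GC content, transcript length and expression level left it at 0.336, which argues against those trends. A change point was called on 12 of 20 chromosomes: genes of chromosome 1 up to position 125873862 had a median of 0.55 and the rest -0.12, genes of chromosome 12 from 91633009 had 0.71, genes of the X chromosome from 113040593 had -0.83, while chromosome 8, without a called change point, had 0.54 as a whole. A candidate explanation is a copy number difference of whole segments: in 100% of the 7 segments with at least 80 genes and a shift of at least 0.4, both quartiles moved with the median by at least 50% of its size. The segments were cut and chosen on these same fold changes, and another cause that shifts a whole region would move both quartiles too. The result therefore cannot tell copy number from such causes, which stay open, and DNA was not analysed here.

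4TO7 replicate 2 stood apart from the other 4TO7 libraries. Of 10816 genes with a 4TO7 mean of at least 100, 519 were at least 2-fold lower there than in both others and 81 at least 2-fold higher, while no other library exceeded 111 lower and 37 higher genes. Replicate 2 was also the 4TO7 library closest to 4T1, at r = 0.843 to 0.848 against 0.809 to 0.822 for replicates 1 and 3. Its score on the first principal component was 98.6, against 117.6 and 117.9 in replicates 1 and 3. Admixed 4T1 RNA is argued against, since 73 genes abundant in 4T1 and near 0 in 4TO7 replicates 1 and 3 summed to 0.112% of their 4T1 level, and so are fibroblast-type cells in replicates 1 and 3, where Col1a1, Col1a2, Col3a1, Dcn and Lum reached at most 26.9 normalised counts. A growth state of the culture may account for it: a list of 48 ribosome biogenesis genes lay 0.61 (log2) higher, at percentile 100 of 10000 random lists matched on expression, and 45 of the 48 were above both other libraries, the list also being 0.74 higher in 4T1 than in 4TO7. Extreme percentiles were not particular to that list in this library. Against 2000 random lists, cell cycle lay at 100, cholesterol synthesis at 99.5 and interferon-stimulated genes at 0. The percentile therefore does not single out a growth state, and it does not address the 519 lower genes. Differences in culture density, on which the labels are silent, stay open and were not tested.

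Zinc finger genes named Zfp were higher in 4TO7 in 144 of 316 cases and higher in 4T1 in 27 (median -0.46, -0.58 with equal totals per sample; camera adjusted p = 0.00032, and adjusted p = 1 with an estimated correlation). Zfp182 had 340 ± 39.8 normalised counts in 4TO7 and 1 read in 4T1, and Zfp667 had 1228 ± 99.9 against 155 ± 13.7. The Zfp gene with the lowest adjusted p, Zfp275, went the other way, at 2049 ± 665 in 4T1 against 0.31 ± 0.54 in 4TO7. Zfp518a did likewise, at 494 ± 186 against 0.31 ± 0.54. After the spline on GC content, transcript length and expression level the median was -0.42, below each of 10000 random lists matched on expression, and the median difference of each gene to its 20 nearest other genes was -0.41, so neither those trends nor position in shifted blocks accounts for the whole pattern. Reads shared between these similar genes stay open, as does a difference between the lines in how the family is regulated, which may be the biological reading but was not tested.

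The 6 libraries can be split into 3 and 3 in 10 ways, so a share under 0.1 cannot arise and these splits cannot tell the real grouping from chance. For the genes called by limma, 1 of the 10 splits, the real one, gave as many in each direction, with 3585 and 3412 genes against 0 in the highest other split (598 at unadjusted p under 0.05), and 1895 and 2030 against 0 for at least 2-fold. For the lists, 6 of the 10 splits gave at least as many calls at the preset correlation. There were 7 in the real split and 5 to 9 in the others, in which limma called 0 genes. Each of the others has libraries of both lines in both groups. Part of the line difference therefore stays in their contrast and the rest widens the spread within groups. Their counts of genes and of lists do not show what chance would give. Chromosome medians lay outside the 95% range of random gene sets for 15 of 20 chromosomes, 13 to 16 with 1 library left out.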
